A study of Rattus norvegicus with 8 samples.

How the data were processed

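The study measured RNA from a rat (Brown Norway) spermatogonial cell line and from primary testis cells, by RNA sequencing. Per the labels, undifferentiated spermatogonia (USg) were expanded in SG medium. Differentiating spermatogonia (DSg) spent 7 days on laminin, with 120 h in SD medium, to which retinoic acid (all-trans) and neuregulin-1 are added. The spermatocyte-enriched group (Spc) held primary germ cells that did not bind laminin, after negative selection on plastic, collagen-I and laminin and 2.5 days in medium with 10% serum. Each group had 2 libraries. For USg, the protocol in the labels places RNA extraction at day 0, before plating on laminin, whereas the sample titles of USg and DSg alike carry T120, so that it is not settled here whether USg and DSg were matched for time. A further 2 samples of anti-Foxa2 chromatin immunoprecipitation were not analysed here.

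The deposited table holds raw read counts per gene symbol for the 6 RNA libraries, with no normalization, as the values themselves show (whole numbers with a different total in each column). Per the submitters' processing notes, the tools used were STAR 2.5.3a, Bowtie2 2.2.3, featureCounts, Subread 1.4.6, edgeR 3.2.4, Picard 1.127 and HOMER, and the builds were rn6 and rn5. The notes give no role for each, and the labels' protocol assigns Bowtie2, Picard and HOMER to the immunoprecipitation. The aligner, build, annotation and strand setting behind the counts are not given in the sources used here. Near-identical paralogs (glutathione S-transferases, alpha globins, histones) and overlapping genes may therefore share or lose reads, and their values are uncertain. The counts of Rn45s and Rn18s differed by less than 5 percent in each library, so reads appear to have been counted for both overlapping genes.

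The table has 16764 symbols, of which 12210 passed the expression filter (filterByExpr of edgeR with the groups, minimum count 10, minimum total count 15) and 4554 did not. Of the symbols, 14450 were current names and 1913 older names in the RefSeq gene table of assembly GRCr8, which served for names and for chromosome membership only (16363 symbols, 97.6%, had a chromosome). No positions are given, since the builds differ. All columns of the table were mapped to a sample by name.

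Counts were normalized with TMM factors and tested with the quasi-likelihood F-test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) in 1 fit of the 6 libraries with a common estimate of the spread, at 3 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 12210 genes, with a threshold of 0.05, and all tests are two-sided. Levels are CPM scaled by the TMM factors, as mean ± SD over 2 libraries. Fold changes are log2 values ± SE, the SE being the absolute log2 fold change over the square root of the F statistic. Where a group held 0 counts of a gene, the fold is given as a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with its exact binomial 95% interval. Intervals and floors cover counting error only. Gene lists were tested with camera (preset inter-gene correlation 0.01), adjusted over the 34 lists that had at least 3 tested members in each comparison: 33 lists written beforehand and the genes of chromosome X. Chromosome Y had 3 genes in the table and was not tested. Counts of members are given over all genes and adjusted over the list alone.

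The design, the gene lists, the rule for named genes and 15 alternatives were fixed before the data were examined. The rule named, per comparison, the 5 highest and 5 lowest log2 fold changes past the threshold with a mean of at least 20 CPM in the higher group and libraries that did not overlap between the groups (symbols of unnamed loci, microRNA and snoRNA left out), up to 4 members per list with at least 5 CPM, up to 2 members per list that went against its direction, and 20 genes whatever their result. Of those 20, 1 is not reported here, Stra8 was not analysed here, and Prm1 did not pass the filter, with counts of 3, 0, 0, 1, 1 and 0 in USg 1, USg 2, DSg 1, DSg 2, Spc 1 and Spc 2. The alternatives were RLE, upper quartile and total-count scaling, no filter, a filter of 5 CPM, DESeq2 1.42.0, limma-voom, the exact test of edgeR, fits of only the 4 libraries compared, a replicate block, each library left out in turn, a test against a 2-fold change, counts thinned to the smallest library, camera with an estimated correlation, and fry. Leaving out the ribosomal RNA genes, and leaving out USg 1 and DSg 1 together, were added after the data were seen.

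Tested on simulated data drawn from these libraries' means and sizes, with 67 genes changed 2-fold, 67 changed 4-fold and 66 changed 8-fold, the fit recovered 0% of 2-fold, 53.7% of 4-fold and 80.3% of 8-fold changes for DSg vs USg, with 4 false calls among 93. For Spc vs USg it recovered 1.49%, 61.2% and 81.8%, with 5 false calls among 101, and for Spc vs DSg 4.48%, 55.2% and 89.4%, with 8 among 107. The simulation gave each gene the same spread in every group, as the fit assumes. In the data the SD of the log2 difference between replicates was 0.95 in USg and in DSg and 0.43 in Spc. The simulated recovery and false calls therefore need not hold for these data, least of all for DSg vs USg. Replicates were compared before averaging: the chi-square per degree of freedom was 79.9 in USg, 43.2 in DSg and 12.5 in Spc, so no 2 libraries were alike within sampling noise. The labels speak of replicate cultures for the cell line and do not say that the Spc libraries came from separate animals, so that p-values measure the spread between these samples, part of which may be technical. Groups of 2 do not allow permutation tests or other splits of the samples.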

Results

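Gene expression was measured in 3 stages of the rat male germ line, each with 2 RNA libraries. Cultured undifferentiated spermatogonia (USg) were compared with the same line after 120 h in a medium with retinoic acid and neuregulin-1 (DSg). The remaining group was primary testis germ cells enriched for spermatocytes (Spc). Spc also differed from the cell line in source, selection and a medium with 10% serum. Differences between Spc and the line therefore cannot be assigned to stage alone. The series title names glutathione metabolism, the pentose phosphate pathway and cysteine biosynthesis, and genes of these pathways are reported in every comparison. Total counts were 2687300 in USg 1, 5697165 in USg 2, 2657291 in DSg 1, 3036091 in DSg 2, 5304373 in Spc 1 and 4864957 in Spc 2.

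The libraries differed in ways that the groups did not explain. Ribosomal RNA genes took 7.81% of counts in USg 1 and 12.4% in DSg 1, and between 0.00377% and 0.734% in the other 4 libraries. These sums hold both Rn45s and Rn18s, at 104940 and 104757 counts in USg 1 and 165091 and 164874 in DSg 1. The same reads appear to have been counted for both genes, so the sums overstate the share of reads. In DSg 2, the 1045 olfactory receptor genes summed to 1673 CPM of the whole library, against 126 to 289 in the other 5, and 96.7% of these genes had a count, against 23.3% in DSg 1. The SD of the log2 difference between replicates was 0.95 in USg and in DSg and 0.43 in Spc. The labels give no sequencing batch or date.

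**Figure D1:**
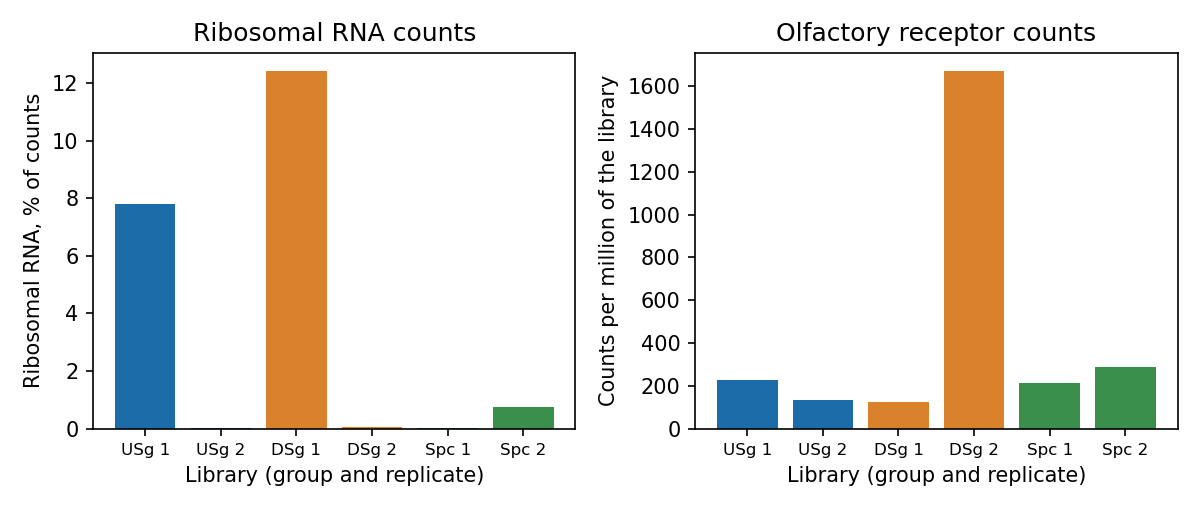
Share of counts on ribosomal RNA genes in percent (left) and CPM of the whole library on 1045 olfactory receptor genes (right), each bar 1 of the 6 libraries, coloured by group. Ribosomal RNA reached 7.81% in USg 1 and 12.4% in DSg 1, and olfactory receptor counts reached 1673 CPM in DSg 2. The ribosomal RNA sums appear to count the same reads for both Rn45s and Rn18s, which overstates the share of reads.

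The comparison of DSg with USg addressed the change of spermatogonia under differentiation medium. DSg had also spent 7 days on laminin, whereas the protocol places USg before plating on laminin. Effects of medium, laminin and time in culture therefore cannot be told apart. The receptor tyrosine kinase Kit, a marker of differentiating spermatogonia, rose from 74.6 ± 16.1 to 579 ± 24.8 CPM (mean ± SD, n = 2; log2 fold change 2.96 ± 0.31, edgeR adjusted p = 0.00556). Cyp26a1, which degrades retinoic acid, rose from 1.14 ± 1.11 to 95.6 ± 21.4 CPM (6.65 ± 0.64, adjusted p = 0.00555), and the related Cyp26b1 rose by 2.65 ± 0.48. Gfra1, the co-receptor for GDNF, fell from 186 ± 4.76 to 21.6 ± 6.57 CPM (-3.12 ± 0.36, adjusted p = 0.00697). The transcription factor gene Foxa2 fell from 123 ± 46.5 to 3.84 ± 0.285 CPM (-4.98 ± 0.52, adjusted p = 0.00556). Across the genome 69 genes were higher and 234 lower in DSg, each by at least 2-fold, of 12210 tested. No gene passed the threshold by edgeR when DSg 1 or DSg 2 was left out. All 303 genes kept their sign, but they had been selected in the fit that held the same libraries, so the kept sign says little. Those fits leave no replicate in DSg, so the lack of calls does not show that the difference was absent. Without USg 1 there were 317 higher and 1184 lower. With all libraries DESeq2 called 206 higher and 563 lower and limma-voom 67 and 220. A fit of the 4 libraries compared called 10 higher and 80 lower, and a test against a 2-fold change 6 and 39. The fit of 6 libraries shares 1 estimate of the spread with Spc, whose replicates differed less (SD of 0.43 against 0.95). That fit may therefore understate the spread in USg and DSg. Of 41 named genes past the threshold, 19 lost their call in a fit of the 4 libraries compared, among them Cyp26b1 (0.0669), 9 with limma-voom, 8 with total-count and 4 with upper quartile scaling.

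The genes with the highest fold changes in DSg, besides Cyp26a1, were the potassium channel gene Kcnd2 (4.85 ± 0.53), Kirrel2 (4.63 ± 0.96), the nephrin gene Nphs1 (4.34 ± 0.51) and Mpped2 (3.70 ± 0.39). The uroplakin gene Upk1b had the lowest (-5.73 ± 0.41), followed by the proenkephalin gene Penk (-5.20 ± 0.92), Foxa2, the kinase gene Sgk1 (-4.67 ± 0.36) and the homeobox gene Noto (-4.59 ± 0.58). Penk was uneven between the USg libraries, at 304 ± 341 CPM, and lost its call with limma-voom (adjusted p = 0.0956). Kirrel2 lost its call with limma-voom (0.0747), total-count scaling (0.0648), the filter of 5 CPM (0.0535), thinned counts (0.0605) and in the fit of 4 libraries (0.0827).

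Genes of undifferentiated spermatogonia were lower in DSg as a list. Of 26 members tested, 10 fell and 0 rose, and 20 fell when adjusted over the list alone (median log2 fold change -2.04, camera adjusted p = 3.66e-24, and 0.0317 with an estimated correlation). Besides Gfra1 these included Lhx1 (-4.24 ± 0.56), T (-3.23 ± 0.48) and Spry4, a feedback inhibitor of FGF signalling (-3.12 ± 0.32). Zbtb16, a marker of undifferentiated spermatogonia, had a log2 fold change of -2.01 ± 0.52 that missed the threshold (adjusted p = 0.0864). It passed as lower without USg 1 (adjusted p = 0.00824), Spc 1 (0.00574) or Spc 2 (0.00803), and with no filter (1.31e-04), DESeq2 (0.00195) or the exact test of edgeR (0.0339), and also without USg 1 and DSg 1 together (9.59e-06). The GDNF and FGF list, which shares members with the former, had 12 of 27 members lower and 0 higher, and 18 lower adjusted over the list alone (camera adjusted p = 2.27e-19, and 0.0317 with an estimated correlation). Its members Egr3 (-3.74 ± 0.58), the MAP kinase phosphatase gene Dusp4 (-3.54 ± 0.42) and the receptor gene Fgfr3 (-3.16 ± 0.32) fell, and Egr3 lost its call with limma-voom (adjusted p = 0.0555).

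In the retinoic acid response list 3 of 19 members rose, Cyp26a1, Cyp26b1 and the meiotic cohesin gene Rec8 (2.00 ± 0.38), 0 fell, and 7 rose adjusted over the list alone. The list was higher (camera adjusted p = 1.98e-04), and its adjusted p with an estimated correlation was 0.211. In the neuregulin receptor list of 7 tested genes, 1 rose over all genes and over the list alone, the receptor gene Erbb3 (2.63 ± 0.38; camera adjusted p = 0.00874, and 0.400 with an estimated correlation). Of 16 genes of differentiating spermatogonia, Kit rose and Bnc2 fell (-1.86 ± 0.32), with 2 higher and 2 lower over the list alone. The list was not called (camera direction higher, median -0.19, adjusted p = 0.806). Of 36 genes of meiotic prophase, Rec8 and Prdm9, whose product marks recombination sites, rose (1.99 ± 0.41 for Prdm9), also over the list alone (camera adjusted p = 0.270). Sycp3, a synaptonemal complex gene, had a log2 fold change of -0.66 ± 0.33 (adjusted p = 0.314). Rec8 lost its call without USg 2 (adjusted p = 0.0727) and in the fit of 4 libraries (0.119), as did Bnc2 in that fit (0.0794) and Prdm9 there (0.150), with limma-voom (0.0745) and with total-count scaling (0.0568). The neuregulin receptor call ended without DSg 1 (0.0623) and with fry (0.05002), and the meiotic list was called higher without DSg 2 (0.0143). Of 20 piRNA genes 0 passed the threshold, with 7 lower and 1 higher over the list alone, and the list, lower in direction, was not called (camera adjusted p = 0.0509, and 0.856 with an estimated correlation). It was called lower without USg 2 (adjusted p = 0.00106), DSg 1 (0.00102), Spc 1 (0.0328) or Spc 2 (0.0309), and with no filter (0.00497), limma-voom (0.0341), total-count scaling (0.0438) or thinned counts (0.0474).

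Of 47 genes of glutathione metabolism, 1 rose and 4 fell in DSg, with 1 and 5 over the list alone, and the list as a whole was not called (camera adjusted p = 0.330). Glutathione peroxidase 2 (Gpx2) fell from 57.7 ± 39.0 to 3.57 ± 0.0960 CPM (-4.02 ± 0.59). The transferase gene Gstp1 (-3.11 ± 0.62) and the aminopeptidase gene Anpep (-1.67 ± 0.32) fell, and so did glutathione reductase (Gsr) from 168 ± 0.358 to 61.2 ± 1.41 CPM (-1.46 ± 0.29, adjusted p = 0.0424), whereas the transferase gene Gstt3 rose (2.12 ± 0.43). The subunits of the rate-limiting glutamate-cysteine ligase were not past the threshold, with log2 fold changes of 0.47 ± 0.28 for Gclc and 0.37 ± 0.45 for Gclm, nor was glutathione synthetase, Gss (-1.19 ± 0.33, adjusted p = 0.102, and 0.0474 without USg 1). In the list of glutathione synthesis and recycling, 1 of 15 members fell, Gsr, and 2 over the list alone (camera adjusted p = 0.278). Targets of the oxidant-responsive factor NRF2 were lower (5 of 30 lower, 0 higher, 6 lower over the list alone, camera adjusted p = 0.00456, and 0.413 with an estimated correlation), among them Gpx2, Gstp1, Tkt and the carbonyl reductase gene Cbr3 (-3.05 ± 0.42). Gsr lost its call without Spc 1 (adjusted p = 0.0896) or Spc 2 (0.0955), with upper quartile (0.0556) or total-count scaling (0.0698) and in the fit of 4 libraries (0.141). Gstp1 lost it without USg 2 (log2 fold change -2.26, adjusted p = 0.0611), with limma-voom (0.132), total-count scaling (0.0674) and 4 libraries (0.118), and Anpep with upper quartile (0.0578) or total-count scaling (0.0809), thinned counts (0.0517) and 4 libraries (0.119). Gstt3 lost it without USg 1 (0.0517), with limma-voom (0.0940) and 4 libraries (0.171), and Gpx2 with limma-voom (0.0528). The NRF2 call ended without DSg 2 (adjusted p = 0.0787) and with fry (0.0833), and the list of glutathione synthesis and recycling was called lower without USg 1 (0.0313) and with no filter (0.0460).

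In the pentose phosphate pathway, transketolase (Tkt) was the 1 member of 20 that fell, from 101 ± 15.2 to 23.6 ± 8.96 CPM (-2.11 ± 0.37, adjusted p = 0.0279, and 0.0814 in the fit of 4 libraries), and 0 rose, with 1 lower and 2 higher over the list alone. The list was not called (camera adjusted p = 0.806, its direction higher although the median was -0.11, which turned to 0.03 with upper quartile or total-count scaling), and its direction turned to lower with no filter and without USg 1, DSg 1, Spc 1 or Spc 2. Pgd had -0.40 ± 0.39, Taldo1 -0.01 ± 0.40 and Tktl1 0.55 ± 0.37, none past the threshold. The transsulfuration list, which also holds genes of the methionine cycle such as Mat1a and Ahcy, was called higher as a set (camera adjusted p = 0.0125, median 0.71). Of its 10 members 0 passed the threshold, over all genes or over the list alone, and its adjusted p with an estimated correlation was 0.693. The call also ended without USg 1 (adjusted p = 0.0713), USg 2 (0.123) or DSg 1 (0.221). Its enzymes of transsulfuration itself stood at 8.43 ± 3.19 CPM in USg and 9.76 ± 2.95 in DSg for Cbs (0.20 ± 0.58), and at 4.29 ± 1.03 and 11.2 ± 0.95 for Cth (1.4 ± 0.55, adjusted p = 0.217). The cystine transporter gene Slc7a11 had 0.62 ± 0.59.

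Immediate early and apoptosis genes were lower as a list (1 of 19 lower, 0 higher, 4 lower over the list alone, camera adjusted p = 6.28e-04, and 0.413 with an estimated correlation), the called member being Ier3 (-3.53 ± 0.44), a growth factor response gene. The call of the list ended with fry (adjusted p = 0.167). In the fibroblast list Thbs1 rose (1.80 ± 0.37) and Timp1 fell (-2.93 ± 0.36), with 3 higher and 3 lower over the list alone (camera adjusted p = 0.854, direction higher, mean 0.04 and median -0.09, which turned positive with upper quartile or total-count scaling). Thbs1 lost its call without USg 2 (0.143) and in the fit of 4 libraries (0.117). Of the 34 lists tested 27 were not called, including those of glycolysis, cholesterol synthesis and chromosome X genes. Without DSg 1 the spermatid and Leydig cell lists were called higher and the proliferation list lower. DSg was then DSg 2 alone, the library with a count on 96.7% of olfactory receptor genes. Expression of spermatid and Leydig cell genes therefore cannot be told apart from that background. Without DSg 2 the cystine and amino acid transport list was called lower, as with no filter (camera adjusted p = 0.0151).

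**Figure D2:**
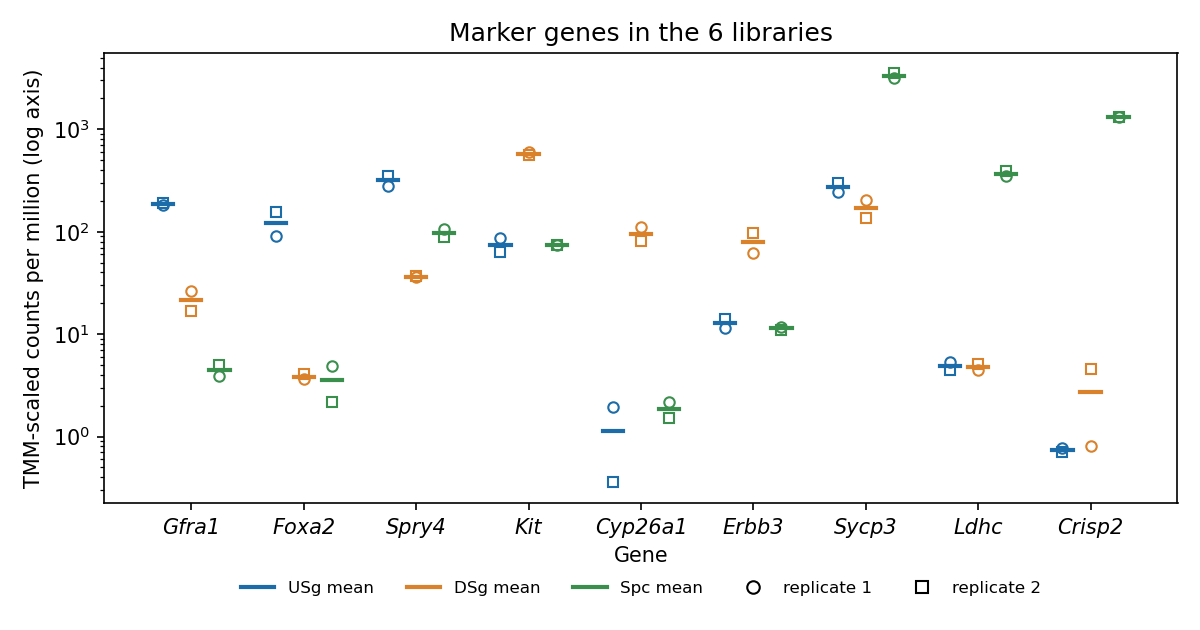
TMM-scaled CPM (log axis) of 9 genes in the 6 libraries. Circles and squares are replicates 1 and 2, horizontal lines the group means, colours the groups. Kit and Cyp26a1 stood highest in DSg, at means of 579 and 95.6, Gfra1 and Foxa2 highest in USg, at 186 and 123, and Sycp3 and Crisp2 highest in Spc.

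The comparison of Spc with USg set primary spermatocyte-enriched cells against the cultured line, so that stage, source and culture differed together. Sycp3 rose from 270.4 ± 40.3 to 3331 ± 251 CPM (3.62 ± 0.36, edgeR adjusted p = 2.75e-04), and Crisp2, a sperm protein gene, from 0.742 ± 0.0421 to 1319 ± 2.85 CPM (10.75 ± 0.68, adjusted p = 1.01e-04). Gfra1 (-5.37 ± 0.41), Zbtb16 (-4.38 ± 0.59) and Foxa2 (-5.09 ± 0.51) were lower in Spc, and Kit did not differ past the threshold (-0.00 ± 0.29). In all, 2185 genes were higher and 2029 lower, 2130 and 1979 of them by at least 2-fold, against 1306 and 1018 without Spc 1 and 1336 and 922 without Spc 2. Among the genes with the highest fold changes 3 had no count in USg. G0s2 was at least 151-fold higher in Spc, Rarres2 at least 139-fold and Cmtm1 at least 122-fold. Tcl1a, Rgs5, Cryga, Igsf21 and Meox1 had the lowest fold changes. Igsf21 (-6.66 ± 0.63) and Meox1 (-6.59 ± 0.45) were measured in both groups, and for Tcl1a, with few counts in Spc, the ratio of USg to Spc was 411 (95% interval 140.3 to 1996).

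Meiotic genes were higher in Spc. Of 36 genes of meiotic prophase 22 rose and 3 fell, the same numbers over the list alone (camera adjusted p = 5.90e-07, and 0.263 with an estimated correlation), with Spata22 (6.08 ± 0.65), Spo11, which makes the breaks that start recombination (5.17 ± 0.67), and Prdm9 (4.48 ± 0.43) among them. Of 26 genes of pachytene and later spermatocytes 18 rose and 1 fell, with 18 and 2 over the list alone (median 3.73, camera adjusted p = 1.37e-13, and 0.10 with an estimated correlation). The lactate dehydrogenase gene Ldhc rose by 6.24 ± 0.38 and Spag6 by 6.73 ± 0.77. Testis forms of glycolytic enzymes rose as a list (6 of 9, 0 lower, 6 over the list alone, camera adjusted p = 1.94e-04, and 0.161 with an estimated correlation), with Pgk2 at 39.7 ± 0.718 CPM (5.50 ± 0.67). Of 14 spermatid genes 5 rose and 3 fell, also over the list alone (camera adjusted p = 0.305), and of 20 piRNA genes 2 rose and 6 fell (camera adjusted p = 0.801), also over the list alone, with Piwil1 at 3.50 ± 0.33 and Piwil4 at -4.72 ± 0.35.

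Undifferentiated spermatogonial genes fell (22 of 26, with 2 higher, and 23 and 2 over the list alone, camera adjusted p = 3.61e-18, and 0.0689 with an estimated correlation), as did those of GDNF and FGF signalling (16 lower and 2 higher of 27, and 18 and 3 over the list alone, 1.46e-08, and 0.10 with an estimated correlation), for example Ret (-4.86 ± 0.34) and Fgfr3 (-5.43 ± 0.36). Proliferation genes were lower (16 of 30 lower and 2 higher, also over the list alone, adjusted p = 5.42e-04, and 0.380 with an estimated correlation), with Rrm2 at -3.50 ± 0.63 and Mcm2 at -2.48 ± 0.40. Cholesterol synthesis genes were lower (13 of 24, 0 higher, 15 over the list alone, adjusted p = 4.62e-04, and 0.263 with an estimated correlation), with Srebf2, the regulator of the pathway, at -2.39 ± 0.33. Serine, glycine and folate genes were lower (9 of 21, 0 higher, 11 over the list alone, adjusted p = 0.0126, and 0.263 with an estimated correlation), with Tyms at -2.39 ± 0.32.

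Markers of testicular somatic cells moved with the Spc group. Of 17 Sertoli cell genes 11 were higher and 0 lower, also over the list alone (camera adjusted p = 1.78e-06, and 0.10 with an estimated correlation), with transferrin (Tf) at 585 ± 3.74 CPM against 7.03 ± 3.4 in USg. Of 8 peritubular myoid genes 6 were higher and 0 lower, also over the list alone (adjusted p = 1.94e-04, and 0.185 with an estimated correlation), with desmin (Des) at 3.65 ± 0.35. Of 15 fibroblast genes 8 were higher and 0 lower, with 9 and 1 over the list alone (adjusted p = 4.19e-08, and 0.263 with an estimated correlation), with decorin (Dcn) at 548 ± 14.0 CPM in Spc and 2.23 ± 0.126 in USg. Macrophage genes were higher in 7 of 11 and lower in 0, with 8 higher over the list alone (adjusted p = 0.0248, and 0.528 with an estimated correlation), for example Cd68 (2.83 ± 0.52), a call that ended without USg 2 (0.0907), with DESeq2 (0.0830), the filter of 5 CPM (0.122), thinned counts (0.118) and fry (0.0502). Endothelial genes were not called (1 higher and 4 lower of 7, adjusted p = 0.127), and Pecam1 was lower (-3.63 ± 0.40). Of the Leydig cell genes tested, Star (7.37 ± 0.45) and Hsd11b1 (6.04 ± 0.99) were higher and the other 2 members not past the threshold (list of 4, the same over the list alone, adjusted p = 0.0282, and 0.263 with an estimated correlation), a call that ended with limma-voom (0.187).

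Glutathione metabolism was called higher in Spc than in USg, with members on both sides: 19 of 47 rose and 10 fell, and 20 and 11 over the list alone (median 0.68, camera adjusted p = 0.0126, and 0.263 with an estimated correlation). The risen members were in part transferases, such as Gstt3 (4.01 ± 2.39 to 359 ± 38.7 CPM, 6.38 ± 0.48) and Gstm2 (6.25 ± 0.53), which belong to families of near-identical genes. Gsr (-2.09 ± 0.30), Gss (-1.11 ± 0.33) and Gpx2 (-4.00 ± 0.57) fell. Gclc (0.67 ± 0.28, adjusted p = 0.0970) and Gclm (-0.01 ± 0.45) did not pass the threshold. The list of glutathione synthesis and recycling had 2 higher, among them Slc7a11, and 2 lower, Gsr and Gss, of 15, also over the list alone (camera adjusted p = 0.873, direction higher, mean 0.24 and median -0.01). Slc7a11 rose from 5.08 ± 2.64 to 54.0 ± 0.591 CPM (3.48 ± 0.57, adjusted p = 0.00219). The somatic cell lists, with 11 of 17 Sertoli genes higher, moved with the same group. The call of the glutathione list ended with limma-voom (adjusted p = 0.104) and without USg 1 (0.0733), and Gss lost its call without USg 2 (0.0579), Spc 1 (0.296) or Spc 2 (0.307) and with no filter (0.0538).

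In the pentose phosphate pathway 7 of 20 members rose in Spc against USg and 1 fell, with 7 and 2 over the list alone, and the list was not called (camera adjusted p = 0.254). The transketolase-like gene Tktl2 rose (1.56 ± 0.31). Tkt (0.61 ± 0.34), Pgd (-0.29 ± 0.39), Tktl1 (-0.07 ± 0.37) and Taldo1 (-1.15 ± 0.41, adjusted p = 0.0559) did not pass the threshold. When Spc 1 or Spc 2 was left out, 2 members of this pathway rose. Tktl2 lost its call without Spc 1 or Spc 2 (adjusted p = 0.0639 and 0.0741), while Taldo1 passed as lower without USg 1 (0.00399) and with upper quartile scaling (0.0453), no filter (0.0337), DESeq2 (0.0302) and the exact test (0.0384). In the transsulfuration list 1 of 10 members rose, Ahcyl2 (1.82 ± 0.31), and 3 fell, Cbs (-2.63 ± 0.66, adjusted p = 0.0149), Mat1a (-2.34 ± 0.61) and Ahcy (-1.08 ± 0.31), with 2 and 3 over the list alone (camera adjusted p = 0.618). Cbs was low in both groups, at 1.36 ± 0.535 CPM in Spc, and lost its call without USg 2 (adjusted p = 0.0709) or Spc 1 (0.123), as did Mat1a (0.0810 and 0.197) and Ahcy (0.375 and 0.25) without Spc 1 or Spc 2, and Ahcy with no filter (0.0579). Cth had 0.01 ± 0.55.

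**Figure D3:**
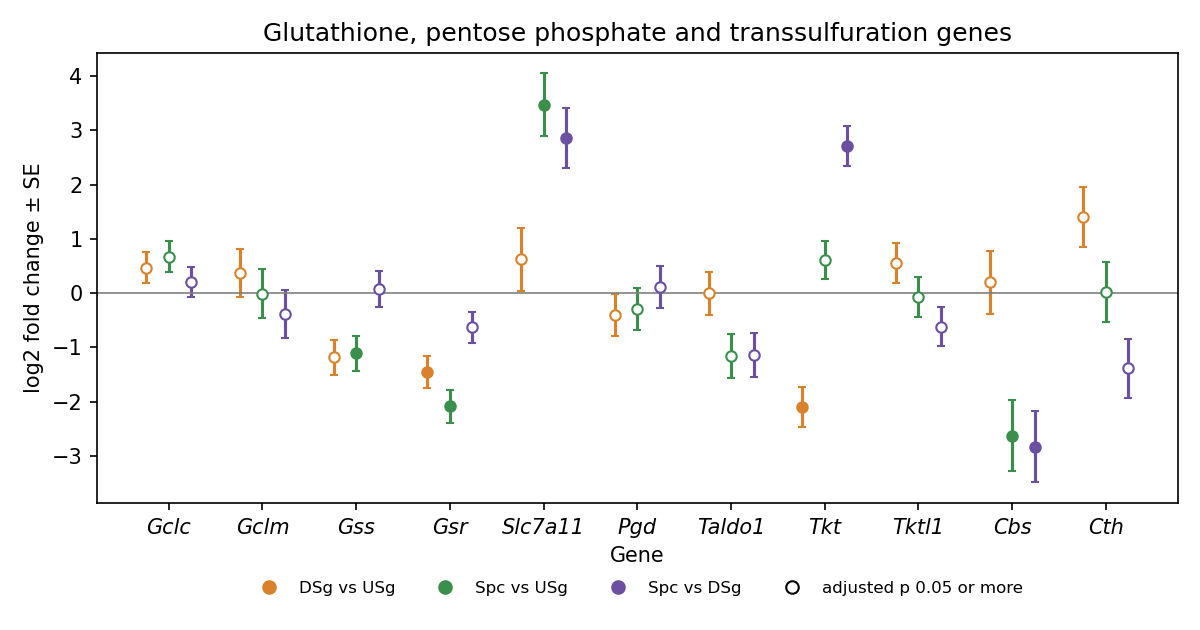
Log2 fold change ± SE of 11 genes of glutathione synthesis, the pentose phosphate pathway and transsulfuration in the 3 comparisons, 2 libraries per group. Filled points are past an adjusted p of 0.05. Gsr and Tkt fell in DSg vs USg, at -1.46 and -2.11, Slc7a11 was higher in Spc than in either other group, and Cbs was lower.

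The comparison of Spc with DSg gave 1806 genes higher and 1433 lower, 1787 and 1405 of them by at least 2-fold. These were 1296 and 789 without DSg 1, 1189 and 884 without DSg 2, 1168 and 474 without Spc 1, and 1231 and 466 without Spc 2. Sycp3 (4.28 ± 0.38), Crisp2 (8.81 ± 0.61) and the linker histone gene Hist1h1t (6.20 ± 0.43, a member of a gene family that can share reads) were higher in Spc, and Kit (-2.96 ± 0.31), Cyp26a1 (-5.66 ± 0.58), Gfra1 (-2.26 ± 0.38) and Zbtb16 (-2.37 ± 0.55) lower. The chemokine gene Ccl2 (8.97 ± 0.54), Ifitm3 (7.84 ± 0.45) and Testin (7.66 ± 0.77) were among the genes with the highest fold changes, and Dmrtc2, with no count in DSg, was at least 43.3-fold higher. Cyp26a1 had the lowest fold change of the genes eligible for naming, followed by Lin28a (-4.39 ± 0.46), Nell1 (-4.28 ± 0.41), Dlk1 (-4.26 ± 0.55) and Ppp2r2c (-4.24 ± 0.50). Foxa2, at 3.55 ± 1.94 CPM in Spc and 3.84 ± 0.285 in DSg, did not differ past the threshold (-0.11 ± 0.54). Gfra1 lost its call without Spc 1 (adjusted p = 0.0596) and Zbtb16 without DSg 2 (0.102). Of the calls 55.8% were higher in Spc, against 43.6% with upper quartile and 45.6% with total-count scaling.

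Meiotic prophase genes were higher in Spc than in DSg (20 of 36 higher and 3 lower, 22 and 3 over the list alone, camera adjusted p = 2.35e-06, and 0.280 with an estimated correlation), as were pachytene genes (19 of 26 higher and 1 lower, 19 and 2 over the list alone, 1.04e-15, and 0.0972 with an estimated correlation). Differentiating spermatogonial genes were lower (9 of 16 lower and 1 higher, 10 and 1 over the list alone, 0.00107, and 0.297 with an estimated correlation), including Kit and Lmo1 (-2.87 ± 0.38). Immediate early and apoptosis genes were higher as a list (10 of 19, 0 lower, 10 over the list alone, 4.44e-04, and 0.285 with an estimated correlation), with Ier3 (6.24 ± 0.48) and Fos (3.60 ± 0.56). So were genes of amino acid and endoplasmic reticulum stress (8 of 16, 0 lower, 8 over the list alone, 0.0138, and 0.327 with an estimated correlation), with Ddit3 at 2.27 ± 0.34, a call that ended without DSg 2 (0.0556). The somatic lists stood higher in Spc here too, with 11 of 17 Sertoli, 6 of 8 myoid and 9 of 15 fibroblast genes higher and 0 lower in each, and 12, 7 and 9 higher over the lists alone, with 1 fibroblast gene lower (adjusted p = 2.25e-08, 3.23e-06 and 2.72e-09, and 0.128, 0.280 and 0.280 with an estimated correlation).

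Of 47 genes of glutathione metabolism 18 were higher in Spc than in DSg and 1 lower, Oplah (-2.17 ± 0.59), with 22 and 6 over the list alone (median 1.07, camera adjusted p = 2.60e-04, and 0.280 with an estimated correlation). Gstp1 rose from 2.36 ± 1.62 to 174 ± 29.8 CPM (6.11 ± 0.65), and Mgst2 (6.80 ± 0.60) and Gsta1 (5.79 ± 0.65) were higher. Gclc (0.21 ± 0.28), Gclm (-0.38 ± 0.45), Gss (0.08 ± 0.33) and Gsr (-0.63 ± 0.29) did not pass the threshold. The somatic cell lists were higher in the same group. Slc7a11 was higher (2.86 ± 0.55, adjusted p = 0.00633). In the pentose phosphate pathway 5 of 20 members were higher and 0 lower, 6 higher over the list alone, and the list was not called (camera adjusted p = 0.241). Tkt stood at 23.6 ± 8.96 CPM in DSg and 154 ± 15.5 in Spc (2.71 ± 0.37, adjusted p = 0.00146). Pgd (0.12 ± 0.39), Taldo1 (-1.15 ± 0.41, adjusted p = 0.0682) and Tktl1 (-0.62 ± 0.36) did not pass. Oplah lost its call without DSg 2 (adjusted p = 0.200) or Spc 1 (0.0728), while Taldo1 passed as lower without USg 1 (0.0228) or USg 2 (0.0189), with upper quartile scaling (0.0337), DESeq2 (0.0447), the exact test (2.81e-04) and 4 libraries (0.00894), and Gsr with the exact test (0.0457).

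The transsulfuration list was lower in Spc than in DSg (3 of 10 lower, 0 higher, 6 lower and 1 higher over the list alone, camera adjusted p = 0.0312, and 0.348 with an estimated correlation). Of the 3 members past the threshold, Mat1a and Ahcy belong to the methionine cycle and Cbs to transsulfuration itself. Cbs (-2.83 ± 0.66, adjusted p = 0.0146), Mat1a (-2.78 ± 0.61) and Ahcy (149 ± 25.0 CPM in DSg, 40.7 ± 4.62 in Spc, -1.87 ± 0.31) were lower, and Cth missed the threshold (-1.39 ± 0.54, adjusted p = 0.0877) but passed as lower with the exact test (0.0113) and 4 libraries (0.0486). Cbs lost its call without DSg 2 (adjusted p = 0.0560) or Spc 1 (0.135), Mat1a without Spc 1 (0.0559) or Spc 2 (0.130) and Ahcy without Spc 1 (0.102), and the call of the list ended without USg 1 (adjusted p = 0.0615), DSg 1 (0.103) or Spc 1 (0.0704) and with DESeq2 (0.0529).

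Counting genes higher in 1 group than in both others, 163 were highest in USg, 23 in DSg and 1408 in Spc. Those of USg included Gfra1, Foxa2, Lhx1, T, Gpx2 and Gsr, and those of DSg included Kit, Cyp26a1, Cyp26b1, Erbb3, Kcnd2, Nphs1 and Mpped2. Because the comparisons shared libraries, overlaps arise by chance. With no effect simulated, the mean over 20 simulations was 0 for USg, 0 for DSg and 0.05 for Spc. Few genes can be called in such a simulation, so it cannot show how lists of the observed sizes would overlap. Independent lists of the observed sizes would share 38.9, 8.10 and 323, numbers that take no account of the shared libraries. With 2 libraries per group the shared group could not be split, so how much of the excess over independent lists comes from the shared libraries is unknown. Without DSg 1 or DSg 2 both the USg and the DSg count were 0, without USg 1 they were 739 and 70, without Spc 1 the DSg count was 15, and the Spc count was 885 without Spc 1 and 907 without Spc 2.

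Genes of chromosome X, 356 tested, were not called as a list in any comparison of all libraries. Of these 6 were higher and 11 lower in DSg than in USg (camera adjusted p = 0.796), 62 and 83 in Spc against USg (0.315), and 48 and 70 in Spc against DSg (0.135), where they were called lower without DSg 2 (0.0357). Over the list alone 11 were higher and 16 lower, 67 and 87, and 50 and 76 in the 3 comparisons.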

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

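In this part every test was chosen after the result was seen, except the comparison of somatic with meiotic genes between the Spc libraries.

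The expression filter removed 1038 of 1045 olfactory receptor genes. In DSg 2 these removed genes summed to 1649.49 CPM of the whole library, against 211 in USg 1 and 123 in USg 2. That sum lies outside the genes tested, which does not show that the tested genes were free of such reads. With all libraries thinned to the smallest total, 96.1% (96.0766) of the olfactory receptor genes still had a count in DSg 2, against 45.8% in the next library, which argues against depth. Expression of these receptors in differentiating spermatogonia is argued against by DSg 1, whose olfactory receptor level was 0.701 (0.701198) times the USg mean. Other receptor families silent in most tissues, 221 genes, stood in DSg 2 at 5.65 (5.65167) times the mean of the other 5 libraries. Genes with 0 counts numbered 232 in DSg 2, against 1118 to 2714 in the other 5 libraries. Reads spread over silent genes in general are therefore a candidate explanation, and the origin of such reads was not tested. Low levels of tested genes in DSg 2 may hold such reads too, which was not tested either.

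Genes of testicular somatic cells were higher in Spc than in USg, with Tf and Dcn at means of 585 and 548 CPM. That all 25 Sertoli, myoid and fibroblast members past the threshold, 100 percent, were higher in Spc restates this and does not test its source. The highest of the Leydig cell genes Insl3, Cyp17a1 and Hsd3b1 reached 1.35% (1.35064) of the Star level of 164 CPM in Spc, and Cyp11a1 stood at 0.938 CPM. These values argue against adult Leydig cells that still expressed those genes as the source of Star. Whether Leydig cells would keep such expression over 2.5 days in medium was not tested. In the Leydig cell list Hsd11b1 went the other way, being higher in Spc than in USg (6.04 ± 0.99, at 95.0 CPM), and its source was not tested. The argument therefore covers only Leydig cells that expressed Insl3, Cyp17a1, Hsd3b1 and Cyp11a1. The list was called higher (camera adjusted p = 0.0282), but not with an estimated correlation (0.263) or limma-voom (0.187). Possible sources are the germ cells themselves and somatic cells left after the selection on plastic, collagen-I and laminin, which would remove many of them. The median log2 ratio of Spc 1 to Spc 2 differed by 0.14 (0.136489) between 25 somatic and 40 meiotic members (permutation p = 0.104, 100000 resamples, two-sided). A constant mixture of cells would give a small difference too, so this test cannot tell the sources apart. Macrophage genes (7 of 11) and red blood cell genes (3 of 4) were also higher in Spc than in USg, with 0 lower. Of 7 endothelial genes 1 was higher and 4 lower.

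The replicates of USg and of DSg differed more from each other than those of Spc. Whether ribosomal RNA took part stays open, since leaving its genes out shifts all log2 ratios between replicates alike, so that their SD, at 100% (100.046) of its value with them, decides nothing. In USg, the fixed fibroblast list stood higher in USg 1 than in USg 2 by a median log2 ratio of 0.67, at percentile 99.6 (99.59) of 10000 random lists matched on expression (Fn1 at 609 and 177 CPM, Col1a1 at 312 and 115), although Timp1 was lower in USg 1, at 84.9 and 111 CPM, so fibroblast or feeder cells in USg 1 are a candidate explanation for part of the difference. In DSg the same list was at percentile 11.9 (11.88), which argues against more such cells in DSg 1 than in DSg 2. For both percentiles the random lists drew genes independently, whereas genes of a cell type can vary together. Either percentile may therefore be too extreme, and each rests on 1 library per side. The ratio between the libraries cannot show whether such cells were present in both. No biological explanation was tested, since the design names none within a group.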

How the results depend on the processing

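The alternatives without the ribosomal RNA genes and without USg 1 and DSg 1 together were chosen after the data were seen, and the others before.

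Over 102 list results, 1990 values under the alternatives stayed on their side of the threshold, 83 of them with the direction turned, while 58 became past it and 87 no longer were, in the same direction. In the 9 results of glutathione, pentose phosphate and transsulfuration among them these numbers were 168, 6, 2 and 19. For 323 named gene results they were 6006, 49, 38 and 408, and 1 turned and passed, Gclm in Spc vs USg, from -0.01 to 0.58 without USg 1 and DSg 1. The pentose phosphate list in DSg vs USg, not called, turned from higher to lower under these 6: no filter, without USg 1, DSg 1, Spc 1 or Spc 2, and without USg 1 and DSg 1. Upper quartile and total-count scaling moved the median log2 fold change of all genes in DSg vs USg from 0.01 to 0.15 and 0.16, and in Spc vs DSg from -0.03 to -0.25 and -0.22, and upper quartile scaling moved it in Spc vs USg from -0.04 to -0.10. The glutathione median in DSg vs USg turned from -0.06 to 0.11 with either. Simulated 2-fold changes were recovered at 0% to 4.48%, with depth not varied and the spread of a gene equal in all groups. With counts thinned to the smallest library, 57 genes were higher and 196 lower in DSg vs USg, 2060 and 1929 in Spc vs USg, and 1718 and 1415 in Spc vs DSg. The causes of the changes below were not tested, except where fewer libraries or a stricter test are the setting.

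In DSg vs USg, the higher and lower counts were 189 and 855 with no filter, 206 and 563 with DESeq2, 10 and 80 in a fit of 4 libraries, and 6 and 39 tested against 2-fold. The exact test called 112 higher, and total-count scaling 141 lower. Against 2-fold there were 1212 and 963 in Spc vs USg and 923 and 493 in Spc vs DSg, where the exact test gave 2802 and 2638 and the fit of 4 libraries 2152 lower. Genes highest in USg, in DSg and in Spc numbered 28, 5 and 742 against 2-fold. Those of USg and DSg numbered 484 and 39 with no filter, 340 and 45 with DESeq2, and 57 and 6 in fits of 4 libraries. The exact test gave 44 for DSg and total-count scaling 94 for USg.

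With a replicate block the counts in DSg vs USg were 168 and 436, and genes highest in USg and DSg 288 and 44. The block called Zbtb16 in DSg vs USg (0.00499), Taldo1 in Spc vs USg (0.0335) and Spc vs DSg (0.0297) and the Leydig list in Spc vs DSg (0.0364), and gave no call to Cyp11a1 (0.0583) and Lyz2 (0.0602) in Spc vs DSg. The labels do not say that the replicate numbers pair the samples, and they were not treated as pairs. The deviations of same-numbered libraries from their group means correlated at 0.25 for USg and DSg, -0.27 for USg and Spc and 0.01 for DSg and Spc. Across genes, which are not independent replicates, USg 1 had a Spearman correlation of 0.9504 with DSg 1 and 0.9505 with USg 2, so a shared origin of USg 1 and DSg 1 stays open.

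Without USg 1 and DSg 1 together only the Spc pair sets the spread, and the higher and lower counts were 2992 and 3335 in DSg vs USg, 4081 and 4165 in Spc vs USg, and 4115 and 4177 in Spc vs DSg, with 2122, 1304 and 2802 genes highest in USg, DSg and Spc. The adjusted p was then 0.0743 for transsulfuration in DSg vs USg and 0.107 in Spc vs DSg, and 0.0862 for glutathione in Spc vs USg. In DSg vs USg, Sycp3, Pgd and Slc7a11 passed under this alternative only.

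Transsulfuration in DSg vs USg had adjusted p = 0.101 with no filter, 0.693 with an estimated correlation and 0.0818 with fry, and in Spc vs DSg 0.0724 with no filter, 0.0529 with DESeq2 and 0.348 with an estimated correlation. Glutathione had 0.104 with limma-voom and 0.263 with an estimated correlation in Spc vs USg, and 0.280 in Spc vs DSg. The pentose phosphate pathway had 0.00368 in Spc vs USg and 0.00645 in Spc vs DSg with fry, which does not compare a list with other genes.

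With each library left out in turn, where a lone library was assumed to vary like the other groups, the counts ranged from 0 to 317 higher and 0 to 1184 lower in DSg vs USg, 1306 to 2288 and 922 to 2274 in Spc vs USg, and 1168 to 2547 and 466 to 1742 in Spc vs DSg. Genes highest ranged from 0 to 739 in USg, 0 to 70 in DSg and 885 to 1739 in Spc. The adjusted p ranged from 0.0168 to 0.221 for transsulfuration in DSg vs USg and 0.0357 to 0.103 in Spc vs DSg, and from 0.00454 to 0.0733 for glutathione in Spc vs USg.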

Other observations

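In this part the genes named as highest in DSg and the examples of imprinted genes were chosen after their values were seen, and both list tests below were written before their results were seen, on lists prompted by genes already seen.

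Beyond the genes of retinoic acid and neuregulin signalling, the 23 genes highest in DSg included Tbx3, Foxn3, Thrb and Igfbp2. The transcription factor gene Tbx3 stood at 81.3 ± 13.6 CPM in DSg against 16.9 ± 4.80 in USg (2.25 ± 0.40, edgeR adjusted p = 0.0298), Foxn3 had a log2 fold change of 1.54 ± 0.31 and the thyroid hormone receptor gene Thrb 1.86 ± 0.36. The insulin-like growth factor binding protein gene Igfbp2 rose from 52.5 ± 32.8 to 306 ± 86.2 CPM (2.53 ± 0.47). None of these 4 passed without DSg 1 (adjusted p from 0.120 to 0.122) or DSg 2 (0.191 to 0.215), or in the fit of 4 libraries (0.0608 to 0.119). Foxn3 also lost its call without USg 2 (0.0763), Spc 1 (0.122) or Spc 2 (0.106), and Thrb without USg 2 (0.0601) or Spc 1 (0.0502) and with thinned counts (0.0539).

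The retinoic acid response list was also higher in Spc than in USg, with 8 of 19 members higher and 1 lower, also over the list alone (camera adjusted p = 0.00335, and 0.185 with an estimated correlation), while in Spc vs DSg 6 were higher and 5 lower (0.383, and 0.0187 with fry). Somatic cell genes were higher in the same group, with 11 of 17 Sertoli, 6 of 8 myoid and 8 of 15 fibroblast genes higher in Spc than in USg. In Spc vs DSg the transglutaminase gene Tgm2 was higher (6.63 ± 0.37) and the receptor gene Rarb lower (-4.16 ± 0.87), a call lost without DSg 1 (adjusted p = 0.0601). Red blood cell genes were higher in Spc than in USg in 3 of 4, with 3 higher and 1 lower over the list alone (adjusted p = 0.00409, and 0.328 with an estimated correlation), a call that ended with limma-voom (0.174). Forkhead A and partner factor genes were lower in 2 of 9 in DSg vs USg, Foxa2 and Foxa3 (-3.43 ± 0.74, adjusted p = 0.0498). Neither passed without DSg 1 (0.108 and 0.139) or DSg 2 (0.145 and 0.217). Foxa3 also lost its call without USg 2 (log2 fold change -2.16, adjusted p = 0.223), and with upper quartile (0.0634) or total-count scaling (0.0857), the filter of 5 CPM (0.0596), limma-voom (0.143), thinned counts (0.0614) and 4 libraries (0.0993). The list was not called (direction lower, mean -0.61 but median 0.28, adjusted p = 0.282), but was called lower with DESeq2 (3.53e-05) and the filter of 5 CPM (0.0336).

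Because Foxa2, Noto, T and Lhx1 fell together in DSg, a hypothesis was that genes of the node and notochord fell as a list. Of 7 other members tested, 0 passed the threshold by edgeR, and camera gave an adjusted p of 0.612 (0.612403), and 0.638 with an estimated correlation, with a median log2 fold change of -0.16, so the hypothesis stays undecided. Another was that imprinted genes were lower in Spc than in USg, prompted by H19 and Dlk1. Of 22 other members tested 4 were higher, such as Ube3a (1.76), and 7 lower, such as Mest (-4.72) and Igf2 (-3.48), and camera gave an adjusted p of 0.271 (0.271409), and 0.399 with an estimated correlation, at a median of -0.29, so it too stays undecided. These were the 2 lists tried.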
